A study of Homo sapiens with 2 samples.

How the data were processed

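RNA of HUES9 embryoid body outgrowths was measured on 1 array for each of 2 conditions, control-OG and SB-OG, each array holding RNA of 3 mixed samples, per the labels. Groups were taken from the sample titles. RNA was extracted with a column kit and labelled with biotin following the array maker's manual, per the labels' protocols. The deposited values are linear intensity values per probe set, 54675 per array, and the software that summarised the probes is not given in the sources used here. Both arrays appear scaled to one level, since the mean without the lowest and highest 2% of probe sets was 150.02 on both. Such scaling fixes the average of an array, so a change in total RNA per cell is not visible. No detection calls were used here. The medians of the log2 values differed by 0.052, under the limit of 0.1 above which they would have been centred, so the values were used as deposited. The log2 values of the 2 arrays correlated with r = 0.84 across probe sets, which are not independent replicates.

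Probe sets were named from the platform annotation of 2016 with updated symbols. Of the probe sets, 41091 had 1 gene, 1801 several, 11721 no name in that table and 62 were controls. Only those with 1 gene were used, giving 19775 genes, of which 19734 matched a gene table of assembly GRCh38.p14 by gene ID. A gene took the value of its probe set with the highest mean log2 intensity over both arrays. The background level of an array was the 95th percentile of 213 probe sets for 172 genes of the olfactory receptor, taste receptor, keratin-associated protein, defensin and late cornified envelope families, assumed not to be used in these cells. Values under that level were set to it before differences were taken. A fold for a gene above background on 1 array only is therefore a lower bound, written "at least", and no fold is given for a gene under it on both arrays. The level was 32.6 on control-OG and 27.6 on SB-OG, so bounds upward start from a higher level than bounds downward. A gene above background on SB-OG only could thus get a negative log2 difference, as TRDN did (18.4 on control-OG, 31.6 on SB-OG, difference -0.04). Levels of different probe sets are not compared with each other.

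With 1 array per condition no test across replicates was possible and none was made. Differences are SB-OG minus control-OG on the log2 scale. Genes were counted at 2-fold. As technical spreads, the SD between probe sets of one gene was taken over 4931 genes with 2 or more probe sets above background on both arrays, and of 1052 such genes at least 2-fold apart, 88 had a probe set of opposite sign. The number of arrays limits the precision of every value. The 33 gene lists, holding 786 genes, were fixed before the data were examined, as were the counts, the alternatives and the rule for named genes, and 67 of the 786 genes had no probe set named for them alone. For lists with at least 5 members above background on 1 array, which 30 had, the median difference is given with a 95% bootstrap interval over members. The percentile of that median was taken among 10000 random lists of the same size, matched in 20 bins of mean expression and drawn with replacement. These intervals and percentiles describe the 2 arrays, with genes as units, and are not tests of the conditions. Lists share some members.

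The named genes were taken from the 12 largest differences in each direction among genes above background on both arrays, the 6 highest lower bounds in each direction, and up to 4 members of each list (6 for the main lists) with the largest difference of at least 2-fold. Genes whose other probe sets above background went the other way were left out of the first 2 parts. XIST, Y-linked genes and genes with a placeholder LOC symbol were left out of these parts too. Other members named in the text, such as those under background or within 2-fold, were chosen after their values were seen. The alternatives were quantile normalization, a lowess correction with a span of 0.4, centring, the mean of all probe sets, only probe sets without _s, _x or _a in their name, no floor, a background at the 99th percentile, a pseudocount of 16, a threshold of 3-fold, and random lists not matched on expression. Scaling on the hybridisation controls was added after seeing the data, for the gene counts only. On simulated arrays of 19775 genes for this comparison, 100 of 100 genes changed by 2 on the log2 scale and 94 of 100 changed by 1.5 were recovered, and 4 unchanged genes passed 2-fold. The simulated differences had less noise than the SD of 0.46 between probe sets of one gene, equal at all intensities. Changes were placed only in genes above background on both arrays, with the dimmest and brightest left out. These counts are therefore not error rates of the calls made here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.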

Results

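Affymetrix arrays were compared, 1 for each culture condition of the human embryonic stem cell line HUES9. Embryonic stem cells at passage 32 were grown as embryoid bodies, floating aggregates in which pluripotent cells begin to differentiate, for 10 days. The embryoid bodies were then plated on fibronectin in a chemically defined medium, and the cells that grew out of them were passaged. One series of cultures received SB-431542, an inhibitor of the type I receptors for TGF-β, activin and nodal, at 10 µM during the embryoid body stage and at 1 µM during the outgrowth stage (SB-OG). The other received the solvent DMSO at 0.01% (control-OG). At outgrowth passage 5, 3 samples of each condition were taken and mixed, and RNA of each mixture was read on 1 array, so n = 1 per condition. No difference below therefore has a replicate check or a p-value. The control-OG array had a median intensity of 22.6 and a background level of 32.6, and the SB-OG array a median of 21.8 and a background level of 27.6, over 54675 probe sets each. Of 19775 genes with a probe set of their own, 11275 were above background on control-OG, 11627 on SB-OG and 10400 on both. Signals of 2 probe sets for one gene gave differences that varied with an SD of 0.46 on the log2 scale, the technical spread within this pair of arrays. Of the 145 genes chosen for naming, 74 had another probe set above background, and in 45 of these at least 1 differed from the printed value by more than 2-fold, in 42 toward no difference. Printed folds are those of the brightest probe set. Values of other probe sets are given as log2 differences, and their size is a lower bound where a dim probe set reached the background level. The ratio of 3′ to 5′ signal, a sign of RNA integrity, was 0.995 on control-OG and 0.958 on SB-OG for GAPDH, and 1.65 and 1.55 for ACTB.

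The comparison asks how growth with the inhibitor bears on the mesodermal differentiation of these cells. Skeletal muscle genes had the highest list median and epithelial markers the lowest among the 30 lists with a median. Under the rule for named genes, WNT2 and DKK1 had the largest negative differences of genes measured on both arrays. Of 12502 genes above background on at least 1 array, 1555 (12.4%) were at least 2-fold higher in SB-OG and 1626 (13.01%) at least 2-fold lower. At least 16-fold differences were seen for 142 genes higher and 91 genes lower in SB-OG. Of the genes 2-fold apart, 48.9% were higher in SB-OG. That share was 76.8% when the SB-OG array was rescaled on the hybridisation controls, which moved all genes up by 0.47 on the log2 scale. List medians were not recomputed with it, and a shift of that size would turn the sign of those for BMP targets, TGF-β family genes, mesoderm factors, adipocyte, IGF axis and cholesterol synthesis genes, trophoblast markers and housekeeping genes. The percentiles given below set each list against other genes of the same arrays.

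Among genes measured on both arrays that passed the rule for named genes, the 12 furthest above control-OG were TNNI1, TNNC2, SMPX, NEB, TTN, CHRNA1, MYH3, SRL, MEF2C, LINC03013, FNDC5 and ZIC1. TNNI1, the slow skeletal troponin I, had an intensity of 53.7 on control-OG and 8620 on SB-OG, a 160.5-fold difference. TNNC2, the fast skeletal troponin C, was 153-fold higher, SMPX, a small muscle protein, was 147-fold higher, and TTN, encoding the giant sarcomere protein titin, was 111-fold higher. Other probe sets gave 3.06 to 4.69 for TTN, 0.07 for NEB, 2.502 for CHRNA1, 4.15 to 6.84 for MEF2C, 3.96 for FNDC5 and 2.21 for ZIC1. By the same rule, the 12 furthest below control-OG were WNT2, DKK1, PDPN, TMEM200A, F3, KRT8, FAP, TENT5A, IL1R1, AMIGO2, DPP4 and BST2. The ligand gene WNT2 had an intensity of 5430 on control-OG and 32.2 on SB-OG, a 169-fold difference. The Wnt antagonist DKK1 was 111-fold lower, the surface glycoprotein PDPN 59.1-fold lower, the tissue factor gene F3 53.3-fold lower and the fibroblast activation protein gene FAP 51.2-fold lower. By another probe set, IL1R1 was at -3.37 and TENT5A at -4.07. Genes above background on 1 array only give lower bounds, ranked here under the rule for named genes. The highest bounds upward were for MYH8 (at least 258-fold), MYOZ2 (at least 174-fold), CKM (at least 147-fold), MYBPH, ACTA1 and CASQ2, and downward for KRT19 (at least 178-fold), TM4SF1 (at least 109-fold), STMN2 (at least 94.5-fold), C3, SLC12A8 and SLPI. The other probe sets were at 2.08 to 7.44 for MYOZ2 and -5.45 to -4.47 for TM4SF1.

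**Figure D1:**
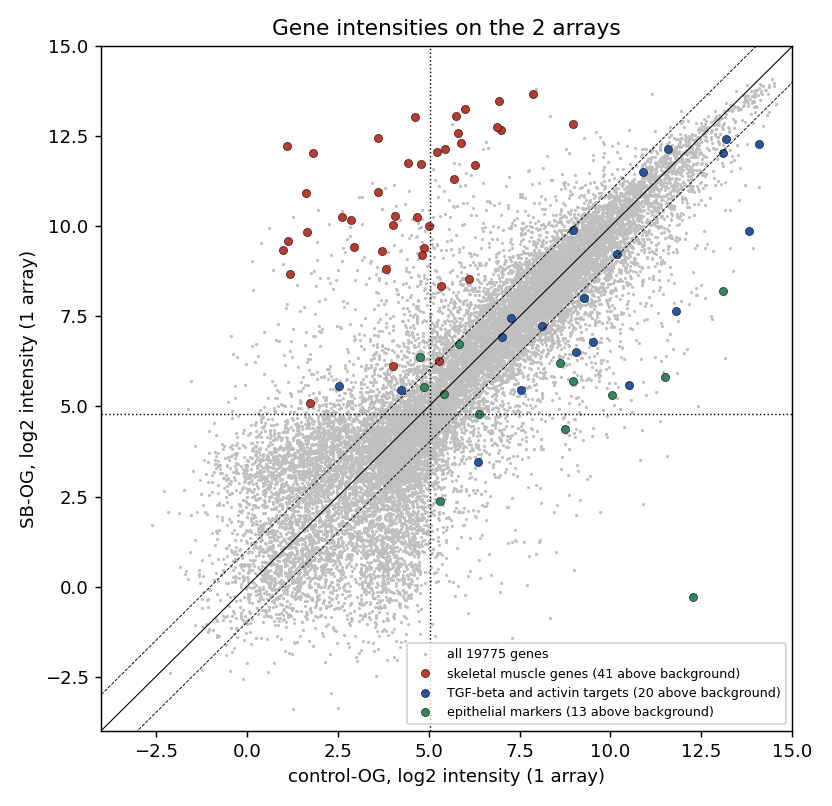
Log2 intensity of each gene on the control-OG array (x axis) and the SB-OG array (y axis), 1 array each, with background levels as dotted lines and 2-fold differences as dashed lines; points are drawn as measured. With values under background set to it, of the 41 skeletal muscle genes above background (red), 39 were at least 2-fold higher in SB-OG, while 10 of 20 TGF-β and activin targets (blue) and 8 of 13 epithelial markers (green) were at least 2-fold lower.

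Of 43 skeletal muscle genes, 41 were above background on at least 1 array, and 39 of these were at least 2-fold higher in SB-OG while none was 2-fold lower. The median log2 difference was 5.26 (bootstrap interval over genes 4.82 to 5.91), above the medians of all 10000 random lists matched on mean expression. The higher members were regulators as well as contractile genes. MYOD1, the myogenic determination factor, had an intensity of 7.25 on control-OG and 1155 on SB-OG, at least 35.5-fold higher. MYOG, the factor of terminal muscle differentiation, was at least 21.1-fold higher, and PAX7, a marker of muscle progenitors, at least 18.2-fold, with its other probe set at 0.24. MEF2C, a transcriptional partner of the myogenic factors, was 85.8-fold higher and CHRNA1, the α subunit of the muscle acetylcholine receptor, 103-fold. MYH3 and MYH8, the embryonic and perinatal myosin heavy chains, reached 11478 and 8392 on SB-OG. The intermediate filament gene DES was 49.3-fold higher and the muscle creatine kinase gene CKM at least 147-fold. MYF6 was near background on SB-OG at 34.4 and CHRNG was 1.96-fold higher. Of the adult fast myosin genes in the list, MYH2 was at least 19.8-fold higher and MYH1 was not above background on either array, nor was the myogenic factor gene MYF5. Myosins, troponins and actins have close paralogues, and the part of each signal that came from a paralogue is unknown.

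Of 20 measured TGF-β and activin target genes, 10 were at least 2-fold lower in SB-OG and none was 2-fold higher. One of the 10 is TPM1, which reversed when only probe sets specific by name were used; 1 of 15 was then 2-fold higher and 7 lower, and without a floor 2 of 20 were higher and 10 lower. The median was -0.99 (-1.94 to 0.06), below those of all 10000 random lists. LTBP2, a latent TGF-β binding protein, was 30.1-fold lower, LMCD1 17.8-fold, and TGFBI, a matrix protein named for its induction by TGF-β, went from 14252 to 942, a 15.1-fold difference. The cyclin-dependent kinase inhibitor CDKN2B was 6.57-fold lower, BHLHE40 5.78-fold, and SMAD7, the inhibitory SMAD of the pathway, 4.24-fold. CCN2, another target, was 1.52-fold higher and ADAM19 1.92-fold. Further probe sets were at -3.68 for LTBP2 and -5.08 to -1.05 for LMCD1. BMP target genes went both ways, with 3 of 12 at least 2-fold higher and 4 lower (median -0.40, -1.42 to 1.16, percentile 5.98 of the random lists). The pseudoreceptor BAMBI was 16.1-fold lower, whereas ID4 was 6.02-fold and SMAD9 3.95-fold higher, with other probe sets for ID4 at 1.09 to 1.42. Among TGF-β family ligands, receptors, antagonists and SMADs, 11 of 33 were at least 2-fold lower and 3 higher, with a median of -0.47 (-1.004 to -0.17, percentile 0.27). The inhibin subunit gene INHBE was at least 18.5-fold lower, the activin antagonists FST and FSTL3 13.2-fold and 8.35-fold, and LTBP1 7.89-fold, with other probe sets for FST at -3.24 to -2.29.

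Markers of pluripotent cells were largely undetected, with 4 of 15 represented genes above background on either array and NANOG at 4.15 and 5.06. The markers POU5F1, CRIPTO and ESRG had no probe set named for them alone and could not be assessed. SOX2 was above background on SB-OG only, at least 4.52-fold, and its other probe set above background was at -0.07. Of 11 primitive streak and early mesoderm genes on the array, 3 were above background, and TBXT and TBX6 were not. KDR, a receptor of early mesoderm and endothelium, was at least 33.8-fold lower in SB-OG. Transcription factors of paraxial and lateral mesoderm divided, with 12 of 35 at least 2-fold higher and 14 lower. EYA4, a transcriptional cofactor in muscle development, was at least 36.4-fold higher, EBF3 14.4-fold, SIX2 8.18-fold and TBX15 7.97-fold. FOXD1 was 19.5-fold lower, the hindlimb factor PITX1 at least 13.2-fold, and FOXF1 and HAND1, factors of lateral and splanchnic mesoderm, at least 11.5-fold and at least 8.72-fold. Other probe sets gave 0.37 to 3.14 for EBF3, 4.12 for EYA4 and -2.46 for PITX1. The list's median of -0.28 (-1.28 to 1.09) lay at percentile 5.88. HOX genes, which mark position along the body axis, were at least 2-fold lower for 3 of 6 genes of paralogue groups 1 to 4 and 4 of 11 of groups 5 to 9, and none was 2-fold higher. Their medians were -0.68 (-1.89 to 0.25, percentile 3.00) and -0.55 (-1.10 to -0.02, percentile 4.14). Without a floor, and also with the pseudocount, 2 of 6 genes of groups 1 to 4 were 2-fold higher and 3 lower. HOXB6 was 12.4-fold lower, HOXB9 at least 8.19-fold, HOXB3 4.36-fold and HOXC4 3.13-fold, with another probe set for HOXB9 at -1.57. Of groups 10 to 13, 3 genes were above background, and HOXC10 and HOXD10 were above it on control-OG only.

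Of 27 epithelial markers on the array, 13 were above background, and 8 of these were at least 2-fold lower in SB-OG. Their median was -2.41 (-4.74 to -0.06), below all 10000 random lists. EPCAM, CLDN3, CLDN4, CLDN7, ESRP1 and GRHL2 were among the markers not above background on either array. KRT8 and KRT18, the keratins of simple epithelia, were 51.3-fold and 29.5-fold lower, and DSG2, a desmosomal cadherin, 26.7-fold. CDH1, the epithelial cadherin, went against the list, at 26.9 on control-OG and 82.8 on SB-OG. Endothelial markers were 2-fold lower for 4 of 8 genes and higher for none (median -1.32, -3.87 to -0.02, percentile 0.05). The receptor genes TEK and FLT1 were at least 14.6-fold and 12.7-fold lower, with other probe sets at -0.61 for TEK and -4.29 to -1.30 for FLT1, and the endothelial cadherin CDH5 was not above background on either array. Among 6 detected endoderm and liver genes, 3 were 2-fold lower, including GATA6 at least 21.8-fold (median -0.91, -3.30 to -0.26, percentile 1.48). Trophoblast markers were 2-fold lower for 2 of 7 genes and higher for 1 (median -0.09, -2.15 to 0.30, percentile 51.9), with HSD3B1 at least 18.7-fold lower. Blood cell markers numbered 5 above background, with 1 higher and 1 lower (median 0.28, -2.97 to 1.70, percentile 91.7), and CD14 was at least 7.81-fold lower.

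Of 29 neural markers on the array, 16 were above background, with 11 of these at least 2-fold higher in SB-OG and 1 lower. Their median was 2.51 (0.74 to 4.13), above all 10000 random lists. PAX6, SOX1, SOX3, OTX2, NEUROG1 and NEUROG2 were among the markers not above background on either array. ZIC1, a factor of dorsal neural tube and somite, was 59.2-fold higher, DCX at least 42.7-fold and the neurofilament gene NEFM 38.3-fold, with other probe sets at 2.21 for ZIC1 and 3.95 for DCX. STMN2, a growth-associated protein of neurons, was at least 94.5-fold lower. Neural crest and Schwann cell markers were 2-fold higher for 6 of 12 genes and lower for 3 (median 1.03, -0.68 to 2.95, percentile 99.9). SOX8 was 48.5-fold higher and ERBB3 at least 30.6-fold, with other probe sets for ERBB3 at 1.95 to 5.11. PAX3 and PAX7, also among the higher members, belong to the skeletal muscle list as well. SOX10, TFAP2B and CDH19 were not above background on either array.

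**Figure D2:**
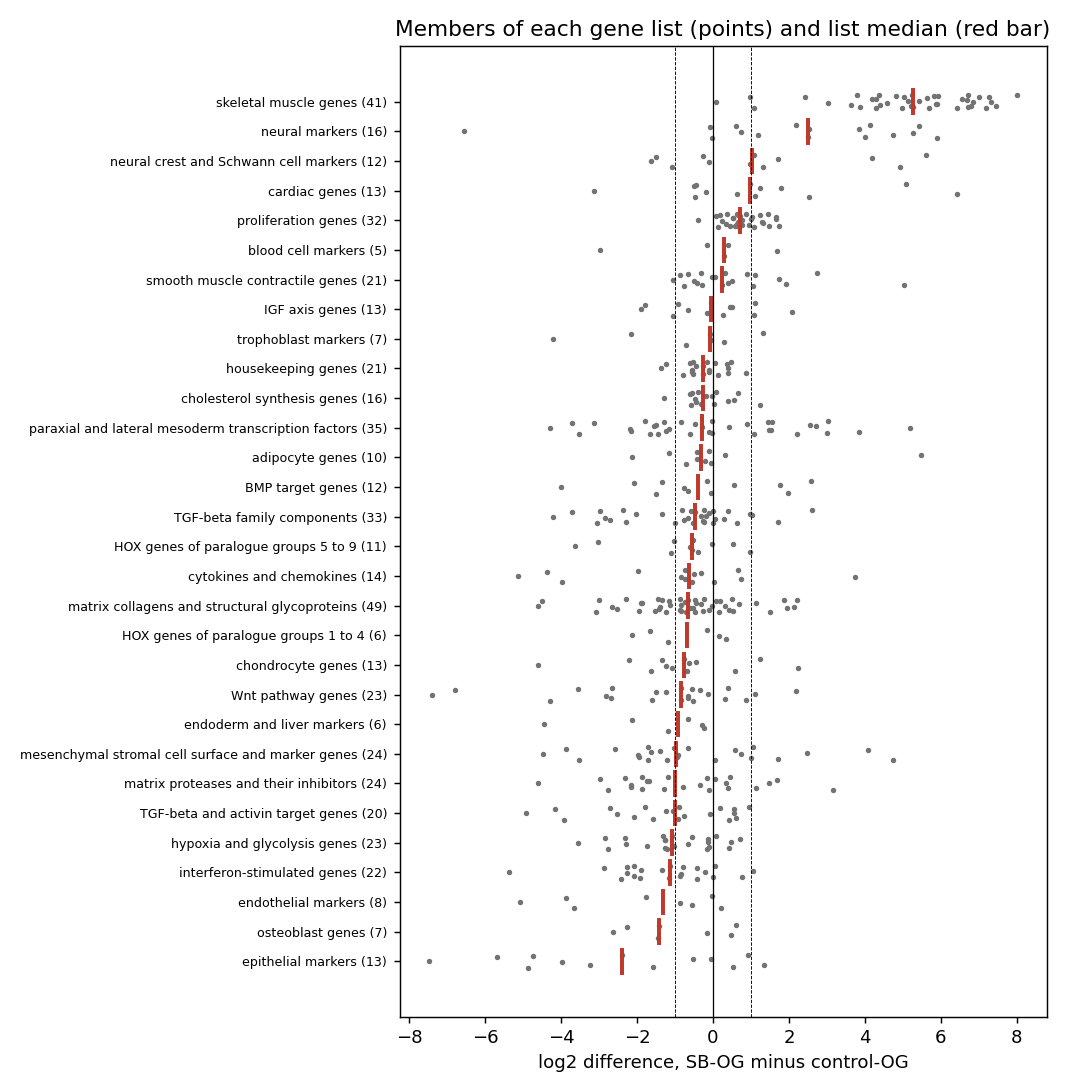
Log2 difference between SB-OG and control-OG (x axis) for each member above background (grey points) of the 30 gene lists with at least 5 such members (y axis, number of members in parentheses), with values under background set to it. Red bars are list medians, from 5.26 for skeletal muscle genes to -2.41 for epithelial markers, and dashed lines mark 2-fold differences.

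Mesenchymal stromal cell genes went both ways. Of 24 measured, 12 were at least 2-fold lower in SB-OG and 6 higher, with a median of -0.99 (-1.70 to 0.58) below all 10000 random lists. The cadherin CDH2 was 22.4-fold lower, the surface glycoprotein THY1 14.6-fold, CD44 3.94-fold, ALCAM 3.86-fold and NT5E 3.27-fold. MCAM was 17.0-fold higher and NES, an intermediate filament of progenitor cells, 26.6-fold with another probe set at 1.92, and ENG was at 128 on control-OG and 132 on SB-OG. Matrix collagens and structural glycoproteins were 2-fold lower for 18 of 49 genes and higher for 6 (median -0.67, -1.13 to -0.27, below all random lists). COL11A1 was 24.4-fold lower, LOX, the collagen cross-linking enzyme, 22.8-fold, COL15A1 8.42-fold, MFAP5 8.05-fold and COL5A1 5.82-fold. Other probe sets gave -5.21 to -3.52 for COL11A1 and -6.27 to -5.42 for LOX. COL1A1, the main chain of type I collagen, went from 18867 to 7025, a 2.69-fold difference with other probe sets at -2.97 to -0.59, and COL14A1 was 4.61-fold higher. Matrix proteases and their inhibitors were 2-fold lower for 12 of 24 genes and higher for 4 (median -0.99, -1.87 to 0.04, below all random lists). SERPINE2 was 24.4-fold lower, TIMP1 7.85-fold and MMP2 4.97-fold, and the urokinase gene PLAU was 8.95-fold higher. The other probe sets gave -0.84 for SERPINE2 and -0.47 for MMP2.

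Of 20 osteoblast genes on the array, 7 were above background, and of these 4 were 2-fold lower and none higher (median -1.43, -2.27 to 0.48, percentile 0.035), with RUNX2, the osteoblast master regulator, 6.16-fold and OGN 4.81-fold lower, and another probe set for RUNX2 at -1.16. SP7 and ALPL were not above background on either array. Chondrocyte genes, 13 of 24 above background, were 2-fold lower for 6 and higher for 2 (median -0.76, -1.34 to -0.46, percentile 0.58), and the median was -0.16 with a higher background level. COL2A1 was at least 4.71-fold higher and SOX5 4.67-fold lower, with another probe set for COL2A1 at 1.10. Adipocyte genes, 10 of 20 above background, were 2-fold lower for 2 and higher for 1 (median -0.31, -0.79 to 0.10, percentile 17.9), the fatty acid transporter gene CD36 at least 44.4-fold with other probe sets at 3.63 to 3.78, and PPARG was not above background. Cardiac genes were 2-fold higher for 6 of 13 and lower for 1 (median 0.97, -0.45 to 1.78, percentile 99.98), and the median was 2.15 with a higher background level. The higher members included MEF2C, ACTN2 at least 33.9-fold and ACTC1 5.73-fold, genes that skeletal muscle also uses, while NKX2-5, TBX5 and MYL2 were not above background. Smooth muscle contractile genes were 2-fold higher for 6 of 21 and lower for 1 (median 0.25, -0.33 to 0.89, percentile 96.8). MYH11 was at least 32.7-fold higher with other probe sets at 0.87 to 3.63, PDLIM7 6.71-fold with 2 probe sets going the other way, and ACTA2 was at 9239 and 10988 with another probe set at 1.60. TPM1 was 2.09-fold lower by its brightest probe set, and its log2 difference was 3.77 when only probe sets specific by name were used.

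Proliferation genes were 2-fold higher in SB-OG for 10 of 32 and lower for none (median 0.71, 0.58 to 0.99, above all random lists). CCNE2 was 3.34-fold, CDC6 3.16-fold, the replication licensing gene MCM2 3.15-fold and CCNA2 2.76-fold higher, while MKI67 was 1.70-fold higher and PLK1 1.31-fold lower. Interferon-stimulated genes were 2-fold lower for 12 of 22 and higher for 1 (median -1.14, -2.01 to -0.61, below all random lists), and the median was -0.43 when only probe sets specific by name were used. BST2 was 41.8-fold lower, IFI35 7.34-fold and ISG15 5.37-fold. Wnt pathway genes were 2-fold lower for 10 of 23 and higher for 2 (median -0.84, -1.61 to -0.35, below all random lists), including RSPO2 at least 19.5-fold and FRZB 11.8-fold besides WNT2 and DKK1. Other probe sets gave -0.36 for RSPO2 and -3.93 to -0.93 for FRZB. Hypoxia and glycolysis genes were 2-fold lower for 13 of 23 and higher for none (median -1.08, -1.27 to -0.15, below all random lists). ANKRD37 was 11.8-fold lower, the lactate dehydrogenase gene LDHA 7.14-fold and the glucose transporter gene SLC2A1 6.83-fold, with another probe set for SLC2A1 at -0.80. Cytokines and chemokines were 2-fold lower for 4 of 14 and higher for 1 (median -0.64, -1.97 to 0.02, percentile 0.46), with CXCL14 at least 34.9-fold and TNFAIP6 20.9-fold lower (another probe set for TNFAIP6 at -3.37) and IL32 at least 13.4-fold higher. IGF axis genes were balanced, 3 of 13 higher and 3 lower (median -0.04, -0.92 to 0.51, percentile 50.9), with IGFBP2 4.26-fold higher and IGFBP3 3.48-fold lower. With the mean of all probe sets, 1 of 12 IGF axis genes was higher and 4 lower, at percentile 94.2. Cholesterol synthesis genes were within 2-fold for 14 of 16 (median -0.26, -0.47 to 0.10, percentile 12.96), with DHCR7 2.42-fold lower and SC5D 2.37-fold higher. Of 21 housekeeping genes, 19 were within 2-fold and the median was -0.25 (-0.54 to 0.05, percentile 13.5).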

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

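The tests of paralogues, the number of arrays, shared muscle genes and spiked controls were chosen after the values they rest on were seen; the lowess correction was fixed beforehand, but its use as a test of brightness came after; the share of pan-neuronal genes was chosen after the neural pattern but before those genes were looked at, and its low-level count and interval requirement were added once its value was seen.

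Probe sets outside the gene comparison also carried signal above the control array. Of 11721 probe sets with no gene name, 256 were at least 2-fold higher on SB-OG than on control-OG and 208 at least 2-fold lower. Of 1801 probe sets with several gene names, 113 were higher and 87 lower.

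The increase of skeletal muscle genes in SB-OG, 39 of 41 at least 2-fold, is the pattern with the largest differences. A trend with brightness or the scaling of the arrays is argued against as the whole cause by the lowess correction, which left the list's median at 5.29 (4.90 to 5.94). Cross-hybridisation among paralogues is argued against as the whole cause by the 9 members without near-identical copies, such as TTN, NEB and DES, with a median of 5.62 (4.38 to 6.85), or 3.53 at each gene's lowest probe set, a check added last, where NEB was at 0.07. A difference between the 2 mixed samples other than the compound cannot be told apart from the compound, since there was 1 array per condition. The blockade of TGF-β and activin receptors therefore stays an untested candidate explanation.

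For the neural list, with a median of 2.51, 1 of 7 pan-neuronal genes above background outside the list (14.3%) was at least 2-fold higher, under the 25% set beforehand as arguing against neurons in the SB-OG culture; the requirement added later leaves them open, since the exact binomial interval of 0.36% to 57.9% contains the 50% set for neurons. RTN1 and MAPT were above background on SB-OG only, at 36.5 and 29.5. They could not reach 2-fold, since their control-OG values were set to the background level of 32.6. A further count, with no level set beforehand, took the 16 represented pan-neuronal genes under 200 on control-OG, above background or not. Its share was 6.25% (0.16% to 30.2%). Of the 19 represented, 12 were not above background on either array, and that count took them as not higher. STMN2 of the neural list went from 2606 to 24.3. SCG2 and UCHL1, both already among the 7, went from 1233 to 112 and from 8656 to 4395. A fall from a high control-OG level does not exclude neurons in SB-OG. Of the neural list, PAX6, SOX1, SOX3, OTX2, NEUROG1, NEUROG2, ELAVL3 and ELAVL4 were not above background on either array, while NEFM, NEFL and MAP2 were higher. Other probe sets gave log2 differences of 0.99 to 3.73 for NEFL and 0.87 for MAP2. Of the 11 list members at least 2-fold higher, 5 (45.5%), NES, NCAM1, ZIC1, ZIC2 and DCX, are also known from muscle cells or dorsal somite. That share leaves open whether the list follows the muscle genes.

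Spiked control transcripts were lower on SB-OG. The 18 hybridisation control probe sets, for RNA added after labelling, had a median log2 difference of -0.47 (SD 0.17 between probe sets). The 24 poly-A control probe sets, for RNA added before labelling, had one of -1.20 (SD 0.23). One scaling factor of the array would move both alike, and the difference of their medians was -0.73, larger in size than the 0.40 of their summed SDs. A different ratio of sample RNA to spiked RNA at labelling may add to it, which was not tested.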

How the results depend on the processing

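Under quantile, lowess and centred values, other probe set rules, no floor, a higher background level and the pseudocount, both gene counts stayed within 1.5 times 1555 and 1626. At 3-fold the counts were 791 higher and 795 lower. Scaling on the hybridisation controls, an alternative chosen after seeing the data, gave 3017 higher and 909 lower, because every gene moved up by 0.47; lists and named genes were not rerun with it. Of the 30 list medians, those that left their bootstrap interval were interferon-stimulated genes (-0.43 with probe sets specific by name), skeletal muscle genes (6.49) and blood cell markers (2.11) without a floor, and cardiac genes (2.15), chondrocyte genes (-0.16) and trophoblast markers (0.39) with the background at the 99th percentile. At that level 6 of 13 cardiac, 8 of 13 chondrocyte and 5 of 7 trophoblast members remained. Among named genes, TPM1 turned to 3.77 with probe sets specific by name, and the cause was not tested. APOA1 (0.14), DGAT2 (0.33) and HOXC5 (0.39) turned with the higher background level. Their SB-OG values (31.1, 3.27 and 17.9) were then raised to a level above their control-OG values (70.1, 61.5 and 59.1). These turns come from the floor, since the measured values were lower on SB-OG. Named genes that kept their sign but differed by more than the SD of 0.46 numbered 65 with the higher background level, 52 with the mean of all probe sets, 30 without a floor, 27 with the pseudocount and 13 with probe sets specific by name, and none under quantile, lowess or centred values. Lists with under 5 members left under an alternative gave no value there. Percentiles crossed 2.5, or the matching upper level, under at least 1 alternative for smooth muscle genes (87.8 to 99.9), TGF-β family genes (0.07 to 7.88), mesoderm factors (0.80 to 29.3), endoderm genes (1.37 to 15.6), chondrocyte genes (0.12 to 8.80), interferon-stimulated genes (0 to 3.99), HOX groups 1 to 4 (0.64 to 18.1) and housekeeping genes (2.27 to 20.2). No paired analysis was possible because each condition has 1 array. Below 32.6 on control-OG and 27.6 on SB-OG, differences have no order.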

Other observations

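The lists and single genes in this part were chosen after the main results were seen, some of them for members already seen, and the mesothelial test was set before the values of its genes were looked at, except for its interval requirement. Genes of excitation-contraction coupling, which link the membrane signal of a muscle fibre to calcium release, were at least 2-fold higher in SB-OG for 10 of 13 and lower for none, with a median of 3.38 (1.85 to 3.90). JPH1, a junctional protein of the calcium release unit, was 16.2-fold higher, HRC at least 23.5-fold and the calcium channel gene CACNA1S at least 10.1-fold. Genes of muscle progenitors and the Notch pathway were higher for 11 of 17 and lower for 2, with a median of 1.14 (0.63 to 3.38). The 2 lower genes were SDC4, at 1165 on control-OG and 175 on SB-OG, and SDC3. HES1 and NOTCH2 were within 2-fold, and DMRT2, EYA2 and CALCR were not above background on either array. HES6 was at least 26.4-fold higher, FGFR4 23.6-fold, NOTCH3 13.2-fold, the Notch ligand genes DLL1 and JAG1 at least 10.6-fold and 4.68-fold, and HEY1 5.75-fold. Also higher were MYMX, a protein of myoblast fusion, at 56.4-fold, and MSTN, the growth inhibitor myostatin, at least 19.5-fold. Other probe sets gave log2 differences of 1.47 for JPH1 and 1.25 to 2.55 for FGFR4.

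Metallothionein genes, which bind zinc and copper, were at least 2-fold lower in SB-OG for 6 of 7, with a median of -3.71 (-4.69 to -2.32). MT2A went from 5254 to 311, MT1X was 25.9-fold lower and MT1E 34.6-fold, with other probe sets at -3.02 for MT1X and -4.04 for MT1E, and their probe sets share near-identical family members. Antigen presentation genes were lower for 8 of 12 and higher for none, with a median of -1.49 (-2.03 to -0.76). HLA-E was 7.03-fold lower with other probe sets at -2.64 to -1.54, the transactivator gene NLRC5 4.82-fold and the peptide transporter gene TAP1 4.79-fold. USP18, an interferon-induced protease, went against the interferon-stimulated genes, at 52.0 on control-OG and 1502 on SB-OG by its 1 probe set. All 13 ribosomal protein genes measured were within 2-fold, with a median of -0.17.

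The epithelial list was lower in SB-OG as were GATA6 and PDPN outside it, and one hypothesis is that mesothelial-like cells were part of control-OG. Of 6 mesothelial genes above background, 3 (50%, exact binomial interval 11.8% to 88.2%) were at least 2-fold lower, namely BNC1, CALB2 and EFEMP1, and ALDH1A2 and GPM6A were at least 2-fold higher, with other probe sets at -1.61 for BNC1 and 1.21 for ALDH1A2. MSLN and UPK3B, abundant in mesothelium, were not above background on either array. Neither were ITLN1 and RSPO1 of the same list, nor WT1 of the mesoderm factor list. The share was at the 50% set beforehand for the hypothesis, but a requirement that its interval lie above 25% was added once the value had been seen, and with it these values leave the hypothesis undecided.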
